A study of Mus musculus with 8 samples.

How the data were processed

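RNA of 4 WT and 4 miR-223KO liver samples, labelled as male and C57BL/6J and all fed a high-fat diet for 3 months, was compared on 8 Agilent 2-colour arrays. Per the labels, RNA was extracted with Trizol and a column, turned into cDNA by an indirect labelling kit and labelled with Cy5, and an assorted mouse total RNA was labelled with Cy3 as the reference on every array, with no dye swap. Per the file headers the arrays (design 014868) were extracted with Agilent Feature Extraction 12.0.3.1 under protocol GE2_1200_Jun14, on a grid named for build mm9. The deposited scanner files hold median spot and local background signals and processed signals as intensity, per the file headers, and the processed signals are background-subtracted and dye-normalised within the array. The deposited LogRatio is the log10 of processed Cy5 over processed Cy3, per the file headers. The authors' table of 40646 probes holds log2 ratios of the processed signals, and its deposited log2 fold change equalled the miR-223KO mean minus the WT mean to within 5.2e-07. The labels do not say that each sample came from a separate mouse, so p-values measure the spread between these samples.

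Of 45018 spots per array, 1639 were controls and 43379 carried 41174 probes. The share of spots well above background was 49.5% to 69.8% in Cy5 and 61.3% to 71.2% in Cy3, no spot was saturated, and 2% to 5.67% of spots had an outlier flag. Median signals were used, since the files hold no mean signals. Local background was subtracted with normexp at an offset of 50, in limma 3.58.1 under R 4.3.3. Local backgrounds with an outlier flag were replaced by the median of the others of that array and channel, because miR-223KO replicate 4 held a Cy5 background of up to 46250. Log2 ratios of Cy5 over Cy3 were normalised within each array by loess, with controls and outlier-flagged spots at weight 0, and the spots of a probe were averaged. Differences given for Cy5 or Cy3 alone were rebuilt from the log2 ratio and the mean log2 signal after loess and Aquantile normalisation between arrays. That step gives all arrays the same distribution of mean signals, so how a change parts between the channels depends on it. Spots flagged as outliers for non-uniformity or within their replicate population, in either channel, were left out. A probe was tested when its Cy5 was well above background on at least 4 of 8 arrays and at least 3 unflagged values stood in each group. Each gene was represented by its brightest probe. Probes were named through RefSeq accessions (28462 probes) or through the symbol in the authors' table, brought up to date where possible (5203 already current, 322 updated, 1377 kept as given), and 5810 had no name. The outlier flags fell on bright genes, and 819 of 15514 named genes above background (5.28%) were lost to them, 442 of them among the 828 with a mean log2 signal above 12.

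miR-223KO and WT were compared with limma (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over 16755 genes and unnamed probes (14695 and 2060) and a threshold of 0.05. The 34 gene lists were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, run on the z-scores of the gene test since some values were missing. Camera with an estimated correlation and fry stood beside it, and p-values were adjusted over the 34 lists. Every list member tested was well above background in liver on at least 4 arrays, which does not exclude cross-hybridisation, and 1 to 11 members of 27 lists stand in another list too. A list score is the mean log2 ratio of its members minus that of all genes on an array, compared by an exact permutation test with a smallest possible p of 0.0286. Genes named in the text are, first, the 10 per direction with the largest change among those past the test with fully separated groups, or, as here where fewer than 5 qualified, the 10 with the smallest unadjusted p and full separation. To these come, for each list, up to 4 members past the test or else the 2 with the smallest p, members past the test adjusted over the list alone, and a fixed set (Mir223, Cxcl10, Wwtr1, Nlrp3, Igf1r, Il6, Tnf, Ccl2, Col1a1, Timp1, Afp, S100a8, S100a9 and Nnt). Other list members given (Cyp2b9, Cyp2b10, Cyp2c37, Nqo1, Cyp7a1, Sqle, Cd36, Flt3, Xcr1 and Zbtb46) and Ren1 and Etnk2 were chosen after their values were seen. Not every gene these rules take is given in the text. Of 33 genes they take with other measured probes, 9 had a probe in the other direction. Genomic positions from the RefSeq table were used only to find neighbours.

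The 8 arrays lay on 2 slides, each with 2 samples of each group, and slide was tried as a block and by values within each slide. Scan, which parted the arrays as slide did, was entered as a block too, so counts of alternatives hold that fit under both names. Aquantile normalisation between arrays kept the changes of Ctse and Slco1a1 at 2.641 and -1.893, so it nearly repeats the main fit. Alternatives covered background correction, normalisation within and between arrays, the Cy5 channel alone, the authors' table, the filter on dim probes, probes per gene, the variance model, the threshold, the list test, and each array left out. Those chosen after seeing the data kept outlier-flagged spots, kept flagged backgrounds as scanned, allowed 2 unflagged values per group, or left Slco1a1 out of its list. A test of genes with miR-223 seed sites was planned and not run, since no 3′ untranslated regions were at hand. The procedure was tested on simulated data, with known changes put into the scanned Cy5 signal of 200 genes on the miR-223KO arrays and all steps repeated. At 4 against 4 it called 50 of 50 genes raised by 2 on the log2 scale, 41 of 50 lowered by 2, 15 of 50 raised by 1 and 8 of 50 lowered by 1, with 8 calls among other genes. The sizes came out smaller than put in, with a median of 1.75 for 2, -1.45 for -2, 0.853 for 1 and -0.79 for -1, so fold changes given here are compressed. Of random lists of 20 genes, all 20 whose log2 ratios were raised by 0.5 were called by camera, by the estimated correlation and by fry, and 2 of the 20 others were called by camera, against 0 with an estimated correlation and 1 with fry. Random genes lack the correlation within real lists, estimated at up to 0.367 (cholesterol synthesis), and no real list shifted by as much as 0.5. These counts thus do not give the power or the false calls for the real lists. Other software was statmod 1.5.0, the data.table package (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.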

Results

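Gene expression was measured in whole liver of male mice on a C57BL/6J background after 3 months on a high-fat diet, in 4 wild-type (WT) and 4 miR-223 knockout (miR-223KO) samples. Each sample was hybridised to its own 2-colour Agilent array, with liver RNA in Cy5 and an assorted mouse tissue RNA in Cy3 as the common reference. The 8 arrays lay on 2 slides, each holding 2 WT and 2 miR-223KO samples. Between 49.5% (WT replicate 4) and 69.8% (WT replicate 2) of the 43379 spots per array that were not controls were well above background in Cy5, with a median Cy5 intensity of 79.5 to 187. A total of 16755 genes and unnamed probes were tested. The number of arrays limited the precision, with a median standard error (SE) of 0.21 on the log2 fold change. All fold changes below are miR-223KO against WT on the log2 scale unless called a fold.

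The comparison of miR-223KO with WT asked which liver transcripts differ when miR-223, a microRNA abundant in myeloid cells, is missing under a high-fat diet. The title of the study places it in steatohepatitis, liver cancer, and inflammatory and oncogenic genes of hepatocytes. Ctse, which encodes the aspartic protease cathepsin E, rose 6.24-fold in miR-223KO liver, from a log2 ratio of -1.75 ± 0.36 (SD, n = 4) to 0.89 ± 0.44 (SD, n = 3). Slco1a1, an organic anion transporter of the hepatocyte membrane with male-biased expression, fell 3.71-fold, from 0.29 ± 0.29 (SD, n = 3) to -1.60 ± 0.23 (SD, n = 4). In limma these changes were 2.64 (SE 0.25, adjusted p = 0.000512, probe A_51_P217906) for Ctse and -1.89 (SE 0.21, adjusted p = 0.00225, probe A_51_P165111) for Slco1a1. They were the only calls, 1 higher and 1 lower, among 772 genes and probes with an unadjusted p under 0.05, where 838 were expected by chance. Every measured miR-223KO value lay above every WT value for Ctse and below it for Slco1a1. Within the slides the change was 2.66 and 2.55 for Ctse, and -1.99 and -1.66 for Slco1a1, and with slide as a block the adjusted p was 0.00169 and 0.00581. Slco1a1 lost its call under 7 of 29 alternatives, with adjusted p of 0.0575 to 0.716. Its WT replicate 3 spot, left out for an outlier flag, read -0.975, nearer to the miR-223KO values than to the other WT values.

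The microRNA itself could not be followed, since no probe carried Mir223 or its host transcript. Ren2, a renin gene, was next among the higher genes, with a change of 1.65 (SE 0.30) that did not pass (adjusted p = 0.208) and within-slide values of 1.74 and 1.55. It was well above background on 2 of 4 WT and all 4 miR-223KO arrays, so its size is uncertain, and the authors' table gives 2.73. It passed with a normexp offset of 16 (2.06, adjusted p = 0.00793) and without miR-223KO replicate 1 (1.92, adjusted p = 0.0239), and over its 28 alternatives the adjusted p ran from 0.00793 to 0.988. Of the 20 genes named by rank with fully separated groups, 18 did not pass, and all 20 had the same direction within both slides. The higher ones included Vldlr, a lipoprotein receptor (1.04, adjusted p = 0.433), Plin4, a lipid droplet coat protein (0.96, adjusted p = 0.394), and H2-Ab1, a chain of an MHC class II molecule (0.96, adjusted p = 0.433). They also included Serpinb8 (0.89), Umps of pyrimidine synthesis (0.85), the olfactory receptor gene Olfr610 (0.83) and Slc13a3 (0.73). The lower ones were Cyp2c54, a cytochrome P450 (-1.40, adjusted p = 0.83), Dhcr7, which catalyses a last step of cholesterol synthesis (-1.02, adjusted p = 0.83), Smim22 (-0.99) and the organic anion transporter Slc22a7 (-0.95, adjusted p = 0.71). Spry4 (-0.84), Tead2 (-0.79, adjusted p = 0.484), Gapdh (-0.75), Dct (-0.75) and Ahdc1 (-0.68) completed them. The Gapdh probe was well above background on only 3 of 4 miR-223KO arrays and no other Gapdh probe was measured, so a fall of this gene is uncertain. Other probes of Spry4 (-0.08) and Ahdc1 (-0.06 and -0.05) hardly changed. For Slc22a7 the difference was -0.48 in Cy5 and 0.46 in Cy3, and for Olfr610 it was 0.40 and -0.43. The reference channel as normalised thus carried a large part of both. Other probes of Serpinb8 and Umps went the other way, at -0.13 for Serpinb8 and -0.18 and -0.05 for Umps. The share of genes with fully separated groups was 3.1%, and chance gives 2.86% for 4 samples against 4.

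**Figure D1:**
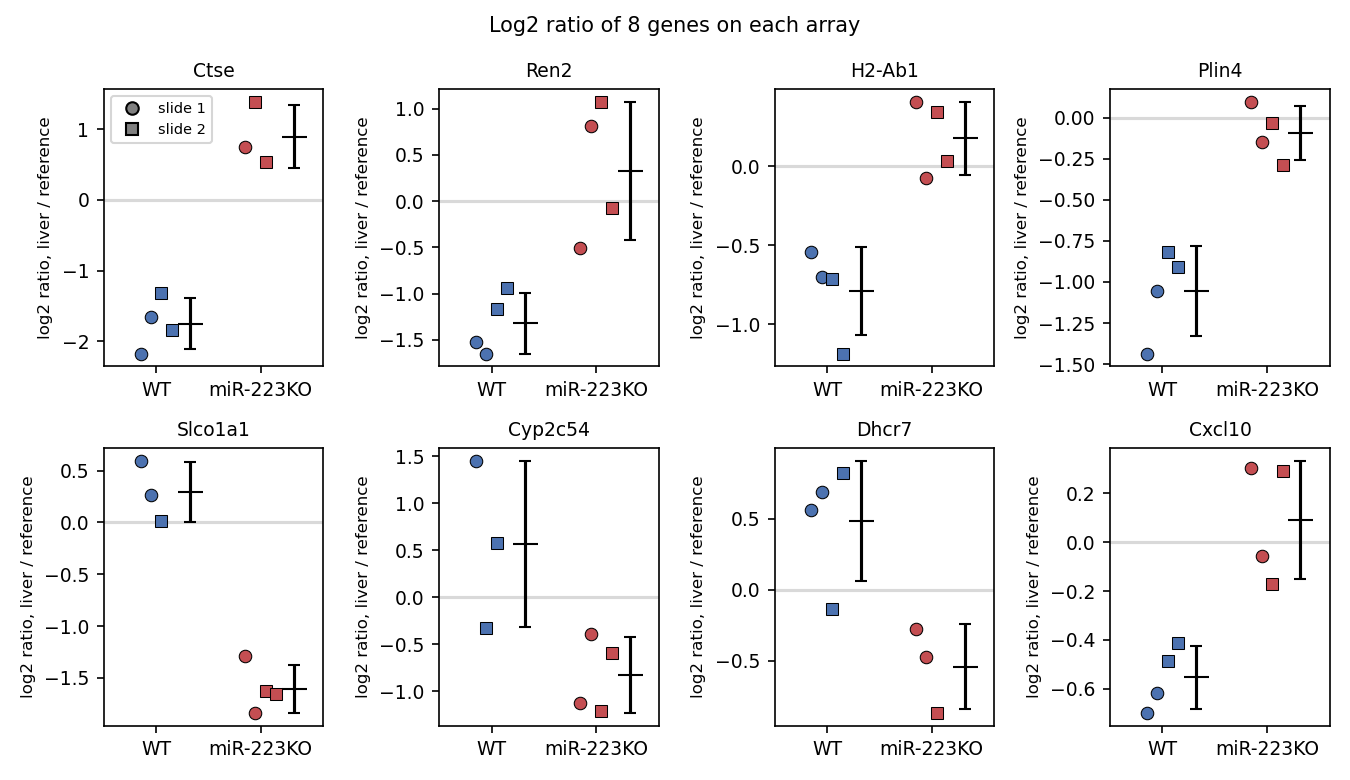
Log2 ratio of liver over reference (vertical axes) for 8 genes on each WT and miR-223KO array, with circles for slide 1, squares for slide 2, and bars for the mean and SD of each group. Ctse (higher) and Slco1a1 (lower) passed the test, and the 6 other genes did not.

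Liver genes with sex-biased expression moved in opposite directions in miR-223KO, although every sample was labelled male. Among male-biased genes, 12 of 14 lay lower and the list shifted by -0.44, the mean log2 fold change of its members minus that of all genes tested. Among female-biased genes, 12 of 15 lay higher and the list shifted by 0.30. Cyp2b13, a female-biased cytochrome P450, stood at 1.14 (SE 0.29), Cyp3a44 at 0.75 (SE 0.25), Cyp2b9 at 0.78 and Cyp2b10 at 0.58, and none of these passed over all genes. On the male-biased side Susd4 stood at -0.95 (SE 0.27), Cyp4a12b at -0.87 (SE 0.29) and Elovl3, a fatty acid elongase, at -0.73 (SE 0.24). With camera of limma the adjusted p was 7.04e-05 for the male-biased and 0.00233 for the female-biased list. With an estimated correlation the adjusted p was 0.301 and 0.318, so neither call held. Over all genes 1 male-biased member passed (Slco1a1), and adjusted over the list alone 4 did (Slco1a1, Susd4, Cyp4a12b, Elovl3), against 0 female-biased members over all genes and 1 adjusted over the list alone (Cyp2b13). Without Slco1a1, a choice made after its value was seen, the male-biased shift was -0.32 (adjusted p = 0.00272 in camera and 0.322 with an estimated correlation). Within the slides the shift was -0.48 and -0.35 for the male-biased list, and 0.47 and 0.07 for the female-biased list.

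Genes of drug and foreign compound metabolism also shifted up, by 0.22 with 19 of 24 members higher. This list holds 6 of the 15 female-biased genes tested, Cyp2b13 among them, and within the slides its shift was 0.40 and -0.02, so slide 2 showed no rise. Cyp2c54 and Cyp2c37 (-0.95) stood on the other side of the list, and Nqo1, a quinone reductase, stood at 0.52. The camera adjusted p was 0.00122, and the adjusted p was 0.478 with an estimated correlation. Over all genes 0 members passed in limma, with 9 at an unadjusted p under 0.05, and adjusted over the list alone 2 did (Cyp2b13 higher, Cyp2c54 lower). Bile acid genes did not shift as a list (-0.11, adjusted p = 0.392, 11 of 19 lower). Slco1a1 was the 1 member past the test, also adjusted over the list alone, while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 0.92 (SE 0.31). NRF2 and oxidative stress genes shifted by 0.15 (adjusted p = 0.0462 in camera and 0.478 with an estimated correlation), with 11 of 17 higher and Gsta2 at 0.76 and Gpx3 at 0.67. That call ended with slide as a block (adjusted p = 0.067) and under 19 of 31 alternatives in all, and the shift was 0.38 on slide 1 and -0.11 on slide 2. It also ended without WT replicate 1 (shift 0.08), WT replicate 2, WT replicate 4 or miR-223KO replicate 1 (adjusted p of 0.054 to 0.403), and the shift was 0.25 without WT replicate 3. Gpx3 differed by 0.35 in Cy5 and -0.32 in Cy3, so a large part of its rise lay in the reference as normalised.

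Cholesterol synthesis genes lay lower in miR-223KO liver, 18 of 22, with a list shift of -0.34. Dhcr7 stood at -1.02 (SE 0.25) and was the 1 member that passed adjusted over the list alone, while 0 passed over all genes in limma and 5 had an unadjusted p under 0.05. Idi1, an isomerase early in the pathway, stood at -0.96 (SE 0.40), and the squalene epoxidase gene Sqle at -0.88. In miR-223KO minus WT, Dhcr7 differed by -0.52 in Cy5 and by 0.50 in Cy3, and Idi1 by -0.38 and 0.58. A large part of both falls thus lay in the reference channel as normalised. The camera adjusted p was 0.000213, and the adjusted p was 0.478 with an estimated correlation. The shift was -0.34 and -0.33 within the slides. Without WT replicate 4 it was -0.13 and the call ended (adjusted p = 0.199), and without WT replicate 3 it was -0.53.

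Lipid uptake and lipid droplet genes shifted up by 0.20, although only 12 of 21 lay higher, and 2 of these stood out. Vldlr at 1.04 (SE 0.21) and Plin4 at 0.96 (SE 0.19) passed adjusted over the list alone, though Vldlr was well above background on only 2 of 4 WT arrays and its other probe read 0.56, and 0 members passed over all genes in limma, with 4 at an unadjusted p under 0.05. Cd36, a fatty acid transporter, stood at 0.54. The camera adjusted p was 0.0115, and the adjusted p was 0.478 with an estimated correlation. The shift was 0.37 on slide 1 and -0.02 on slide 2, and the call ended without WT replicate 1 (shift 0.13) or miR-223KO replicate 1 (adjusted p of 0.131 to 0.141). Fatty acid synthesis did not pass (0.08, adjusted p = 0.326), though Elovl6 stood at 0.89 and Lpin1 at 0.84. PPARA targets and fatty acid oxidation did not pass either (0.12, adjusted p = 0.116), with Ehhadh at 0.53 and Pex11a at 0.40. This list passed in camera under 6 of 31 alternatives (adjusted p of 0.00212 to 0.0419), among them the one that kept outlier-flagged spots, chosen after seeing the data, with 37 members tested in place of 21 and a shift of 0.16. Glucose metabolism did not pass (0.05, adjusted p = 0.581), where Foxo1 at 0.63 (SE 0.18) passed adjusted over the list alone and the glycogen phosphorylase gene Pygl stood at -0.63. Other probes of Foxo1 and Pygl went the other way, at -0.10 for Foxo1 and 0.20 for Pygl. Adipocyte genes did not pass (0.11, adjusted p = 0.392), with Cidec at 0.79 and with Car3 at 0.58 past the test adjusted over the list alone.

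**Figure D2:**
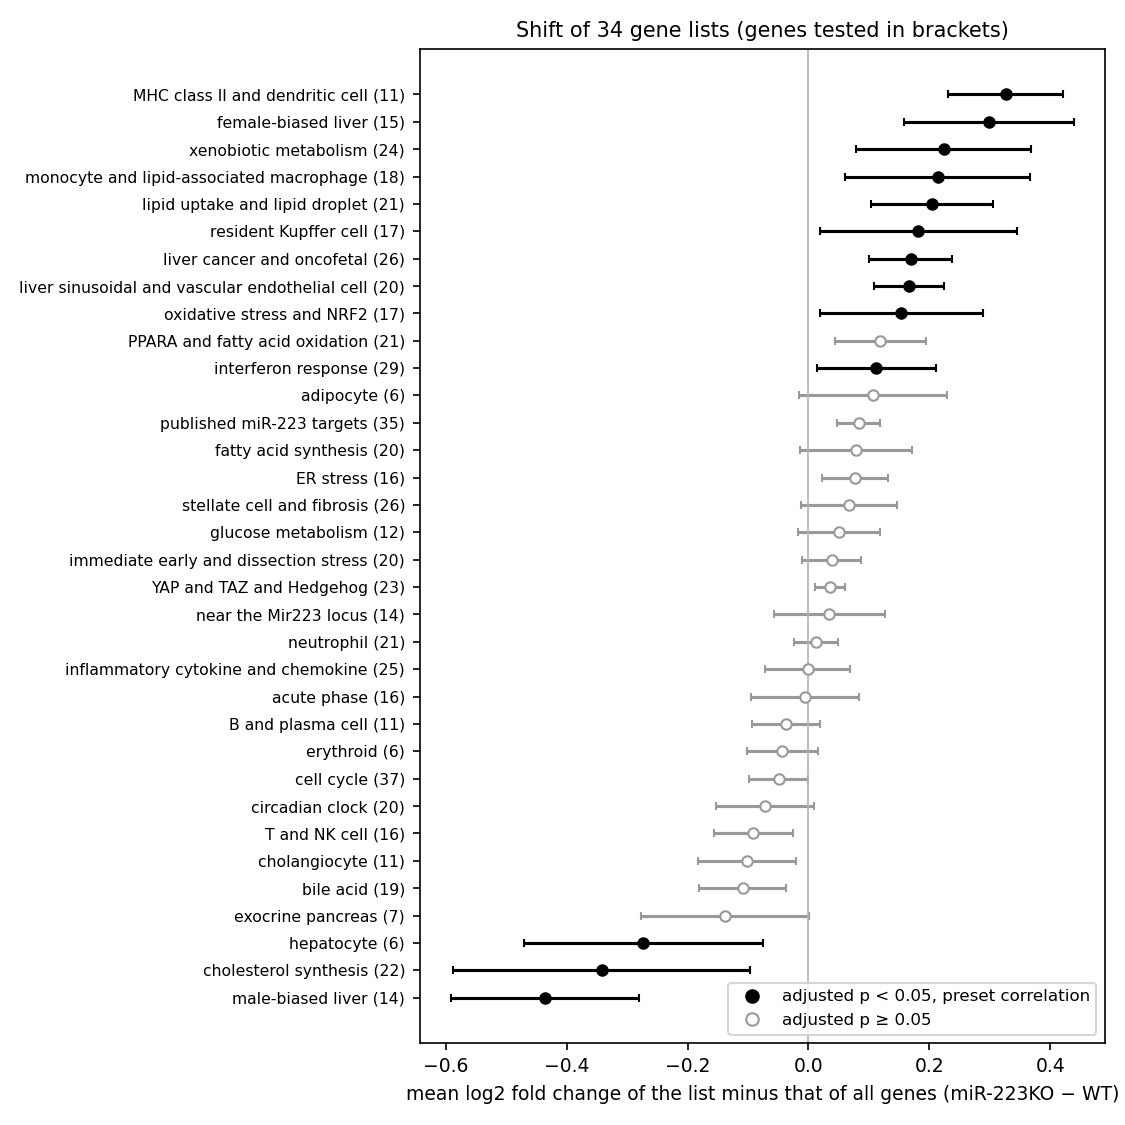
Shift of each of the 34 gene lists (horizontal axis, mean log2 fold change of the list minus that of all genes tested, miR-223KO minus WT), with bars for the SE between arrays and the number of genes tested in brackets. Filled points mark the 13 lists past the test with a preset correlation, 10 higher and 3 lower, of which 0 passed with an estimated correlation.

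Genes of MHC class II antigen presentation and markers of macrophages and endothelium lay higher in miR-223KO liver, while those of lymphocytes, neutrophils, stellate cells and bile duct cells showed no list shift past the test. MHC class II and dendritic cell genes shifted by 0.33 with 8 of 11 higher, led by H2-Aa at 1.07 (SE 0.29), H2-Ab1 at 0.96 (SE 0.20) and H2-Eb1 at 0.78 (SE 0.27), which present peptides to helper T cells. H2-Aa and H2-Eb1 were highest on miR-223KO replicate 1, at 1.44 and 1.79, against at most 0.22 and 0.89 on the other miR-223KO arrays. H2-Eb1 differed by 0.39 in Cy5 and -0.39 in Cy3, so the reference as normalised carried a large part of its rise. H2-Aa (1.09 in Cy5, 0.02 in Cy3) and H2-Ab1 (0.82 and -0.14) rose mostly in Cy5. The 3 lower members of the list were the dendritic cell genes Zbtb46 (-0.25), Xcr1 (-0.17) and Flt3 (-0.15), none past the test. H2-Aa, H2-Ab1 and H2-Eb1 passed adjusted over the list alone, and 0 passed over all genes in limma, with 4 at an unadjusted p under 0.05. All 4 miR-223KO scores of this list lay above all 4 WT scores, 0.11 ± 0.19 (SD) against -0.22 ± 0.04 (SD), with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 allow (0.416 when adjusted over the 34 lists). Its camera adjusted p was 0.00419, and the adjusted p was 0.301 with an estimated correlation. Within the slides its shift was 0.42 and 0.23. Monocyte and lipid-associated macrophage genes shifted by 0.21, with 15 of 18 higher, Trem2, a receptor of lipid-associated macrophages, at 0.57 and Cd68 at 0.52 (adjusted p = 0.0115 in camera and 0.478 with an estimated correlation). Resident Kupffer cell genes shifted by 0.18, with 11 of 17 higher, Csf1r at 0.54 and Clec1b at 0.52 (adjusted p = 0.0208 in camera and 0.478 with an estimated correlation). Endothelial genes shifted by 0.17, with 14 of 20 higher, Ptprb at 0.63 and Flt4 at 0.47 (adjusted p = 0.0119 in camera and 0.301 with an estimated correlation). The other probe of Ptprb stood at -0.03. Flt4 differed by 0.21 in Cy5 and -0.27 in Cy3, so more of its rise lay in the reference as normalised. Within the slides the shift was 0.36 and 0.09 for monocytes and macrophages, 0.30 and 0.05 for Kupffer cells, and 0.21 and 0.12 for endothelium. Without WT replicate 1 the calls of these 3 lists ended (adjusted p of 0.112 to 0.141), that of the monocyte and macrophage list also without WT replicate 4 or miR-223KO replicate 1, and that of the Kupffer list also without WT replicate 2, WT replicate 4, miR-223KO replicate 1 or miR-223KO replicate 3 (all at 0.0832 to 0.205). The monocyte and macrophage shift was 0.12 without miR-223KO replicate 1 and 0.34 without WT replicate 3, and the Kupffer shift 0.31 without WT replicate 3.

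Hepatocyte genes shifted by -0.27, with all 6 measured members lower, Alb at -0.66 and Apoa1 at -0.55 (adjusted p = 0.0386 in camera and 0.478 with an estimated correlation). Alb differed by -0.27 in Cy5 and 0.39 in the Cy3 reference, and Apoa1 by -0.17 and 0.38, so more of both falls lay in the reference as normalised. Only 6 of the 18 members on the array were tested, since outlier flags removed bright spots, and the call ended under 19 of 31 alternatives. With those spots kept, a choice made after seeing the data, 18 members were tested and the shift was -0.07 (adjusted p = 0.322, in a range up to 0.654 over the other settings that ended it). The shift was -0.05 on slide 1 and -0.52 on slide 2. Neutrophil genes, from the cell type known for high miR-223, did not shift (0.01, adjusted p = 0.801, 8 of 21 higher). Their median fold change was -0.01, of the other sign to the test, with S100a9 at 0.59 and Prtn3 at 0.21, and S100a8 was well above background on 3 of 8 arrays and not tested. T and NK cell genes stood at -0.09 (adjusted p = 0.232), with Icos at -0.42 (other probe 0.23) and Ncr1 at -0.31, and B and plasma cell genes at -0.04 (adjusted p = 0.606), with Ighm at -0.32 and Ms4a1 at 0.40. Cholangiocyte genes stood at -0.10 (adjusted p = 0.339), with Krt7 at -0.58 and Sox9 at -0.36, and erythroid genes at -0.04 (adjusted p = 0.606), with Klf1 at -0.32. Exocrine pancreas genes stood at -0.14 (adjusted p = 0.202), with Cela3b at -0.29 and Ctrb1 at -0.35.

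**Figure D3:**
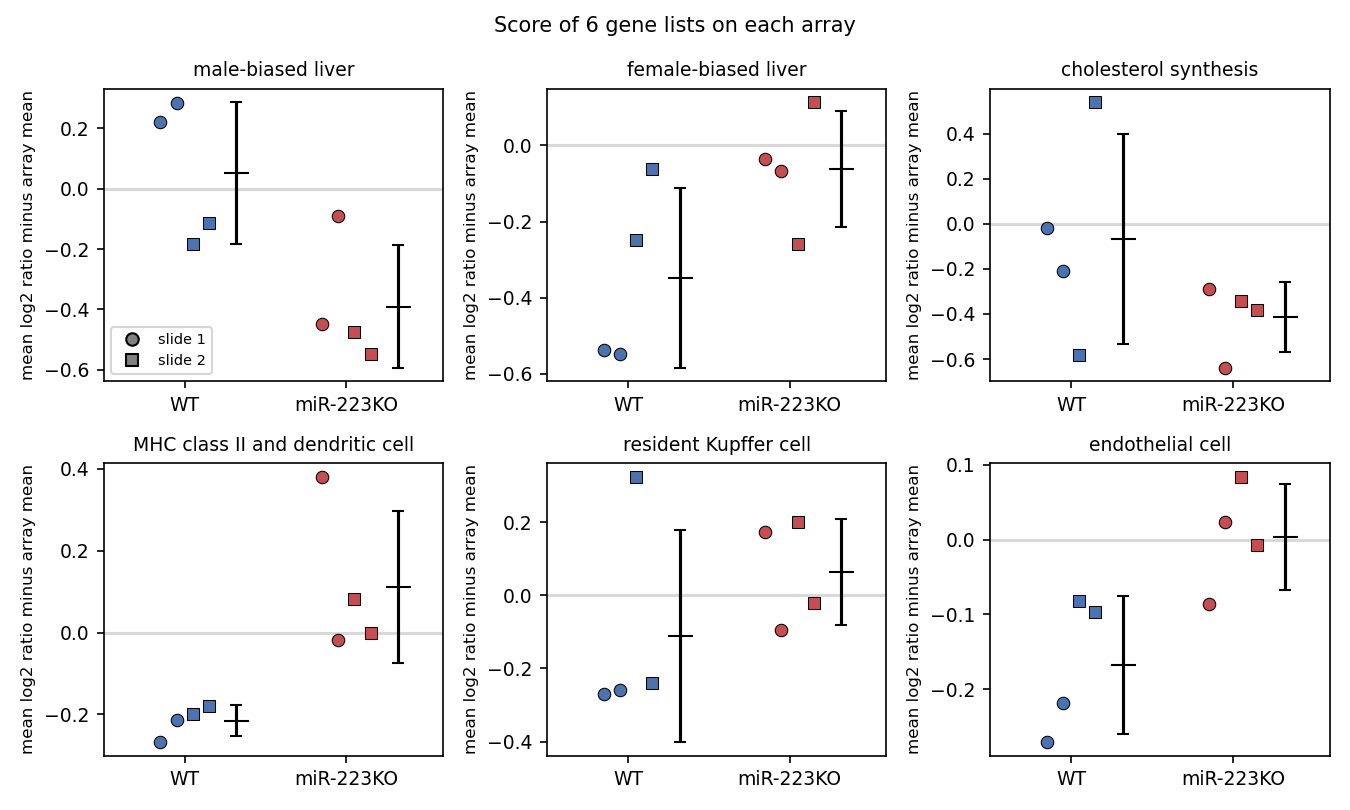
Score of 6 gene lists on each array (vertical axes, mean log2 ratio of the list minus the mean of all genes on that array), with circles for slide 1, squares for slide 2, and bars for the mean and SD of each group. The MHC class II and dendritic cell scores of miR-223KO and WT did not overlap, whereas Kupffer scores did, with WT replicate 3 at 0.33.

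Published miR-223 targets, the genes that losing the microRNA would be thought to release, lay higher as often as 21 of 35, and their shift of 0.08 did not pass (adjusted p = 0.101 in camera). It passed under 3 of 31 alternatives, with median centring, every probe on its own or the mean of a gene's probes (adjusted p of 0.0181 to 0.0404), and had an adjusted p of 0.319 with an estimated correlation. Cxcl10, a chemokine that draws T cells, stood at 0.65 (SE 0.18, adjusted p = 0.981) and was well above background on 1 WT and all 4 miR-223KO arrays. The size of its change is thus uncertain, and the authors' table gives 1.43. The named targets Wwtr1 (TAZ, 0.15), Nlrp3 (0.17) and Igf1r (0.12) did not pass, each with an SE of 0.20 to 0.21. In this list 0 members passed over all genes or adjusted over the list alone in limma, with 3 at an unadjusted p under 0.05. Inflammatory cytokine and chemokine genes did not shift (mean -0.00, adjusted p = 0.878), with a camera direction opposite in sign to the mean, the median and fry. Tnf stood at 0.01, Ccl2 at -0.11 and Cxcl16 at -0.37, and Il6 was well above background on 0 of 8 arrays. Interferon response genes shifted by 0.11, with 20 of 29 higher, Gbp6 at 0.51 and the immunoproteasome gene Psmb8 at 0.39 (adjusted p = 0.0324 in camera and 0.478 with an estimated correlation). Other probes went the other way at 0.22 for Cxcl16 and -0.05 for Psmb8. The interferon shift was 0.04 and 0.19 within the slides, and its call ended without WT replicate 4, miR-223KO replicate 1 or miR-223KO replicate 4 (adjusted p of 0.205 to 0.43) and under 5 other settings (up to 0.216). The interferon shift was 0.05 without miR-223KO replicate 4, 0.06 without WT replicate 4 and 0.17 without miR-223KO replicate 3.

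Liver cancer and oncofetal genes shifted up by 0.17, with 21 of 26 higher. Anxa2, a calcium-dependent membrane-binding protein, stood at 0.84 (SE 0.22) and passed adjusted over the list alone, while 0 members passed over all genes in limma and 3 had an unadjusted p under 0.05. Ly6d stood at 0.70 and Afp, the fetal liver marker, was well above background on 0 of 8 arrays. All 4 miR-223KO scores of this list lay above all 4 WT scores (exact two-sided permutation p = 0.0286, and 0.416 when adjusted over the 34 lists). The camera adjusted p was 0.00522, the adjusted p was 0.318 with an estimated correlation, and the shift was 0.20 and 0.14 within the slides. The call ended without WT replicate 1 (shift 0.11, adjusted p = 0.116), the array on which Anxa2 stood farthest below the other WT arrays. Genes of YAP, TAZ and Hedgehog signalling did not shift (0.04, adjusted p = 0.606), although Tead2, a partner of YAP and TAZ, passed adjusted over the list alone at -0.79 (SE 0.17), with Crim1 at 0.37. Crim1 differed by 0.05 in Cy5 and -0.33 in Cy3, so most of its rise lay in the reference as normalised. Cell cycle genes did not shift (-0.05, adjusted p = 0.443), with Mcm6 at -0.49 and Ccne1 at -0.45, whose other probe stood at 0.40. Stellate cell and fibrosis genes did not shift (0.07, adjusted p = 0.412), with Col1a1 at 0.35 (SE 0.31), Timp1 at 0.27 (SE 0.24), Pdgfrb at 0.24 and Fn1 at -0.21.

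Acute phase genes did not shift (mean -0.01, median 0.00, adjusted p = 0.834), with Fga at -0.82 and Lcn2 at 0.81. ER stress genes stood at 0.08 (adjusted p = 0.392), with Creld2 at 0.62 and Hyou1 at -0.28, and circadian clock genes at -0.07 (adjusted p = 0.339), with Bhlhe41 at -0.40 and Per3 at -0.33. Immediate early genes stood at 0.04 (adjusted p = 0.606), with the phosphatase gene Dusp1 at -0.84 and Jun at 0.37. Of the 34 lists, 23 had 0 members past the test over all genes or adjusted over the list alone in limma, with 27 of their 429 members at an unadjusted p under 0.05, a gene in several lists counted in each. With an estimated correlation 0 lists passed and 5 had an unadjusted p under 0.05, and fry gave the same counts. The exact permutation test of list scores gave 0.0571 to 0.314 for the 11 other lists past camera, with 0.0857 for the male-biased and 0.143 for the female-biased score.

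Genes on chromosome X around Mir223 showed no excess of differences. Of 32 genes within 5 Mb, 0 passed in limma and 2 had an unadjusted p under 0.05, a share of 6.25% against 4.68% elsewhere (Fisher's exact test, two-sided p = 0.661). Within 10 Mb it was 3 of 62 genes (exact test, p = 0.766). The list of genes near the locus, fixed by name, stood at 0.03 (adjusted p = 0.606), with Msn, a membrane cytoskeleton linker, at 0.43 and Gpr165 at -0.28. Nnt, a mitochondrial transhydrogenase gene on chromosome 13, stood at 0.93 (SE 0.25, adjusted p = 0.981), with other probes at 0.47 and 1.503.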

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

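The tests of donor-strain DNA, of the Cy3 channel, of the sequence shared by renin genes, of the hepatocyte share and the count of splits even over the slides were chosen after the results were seen, while those of single arrays and of dye bias were set before. A search for samples far from the 3 others of their group, by the gap to the nearest sample over the range of the group, picked 8 of 234 groups (3.42%), and chance picks about 1 in 20 groups, 5%. Among WT samples, Anxa2 on replicate 1 read -1.37 against -0.57 to -0.56 on the others (gap over range 0.979), and Apoa1 on replicate 4 read 2.40 against 1.18 and below (0.869). Flt4 on WT replicate 4 read 0.78 against 0.41 and below (0.864), and Fn1 on WT replicate 3 read 0.65 against 0.33 and below (0.859). The WT list scores so picked were the Kupffer score of replicate 3, 0.33 against -0.24 and below (0.95), and the exocrine pancreas score of replicate 1, -0.06 against 0.27 and above (0.836). In miR-223KO they were the YAP, TAZ and Hedgehog score of replicate 4, -0.05 against -0.03 (0.839), and the NRF2 score of replicate 1, 0.29 against 0.02 and below (0.88).

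Ctse was higher in miR-223KO, and Ren2 (1.65) and Ren1 (1.15) stood higher without passing the test, with Ctse and Ren1 both on chromosome 1 within 10 Mb of Ptprc. A difference in the Cy3 reference channel is argued against, since the Cy3 signal of Ctse stood at -0.398 (SE 0.235) in miR-223KO minus WT while its Cy5 signal stood at 2.24. Donor-strain DNA kept around Ptprc during breeding may account for the pattern, though the labels give both groups the same strain. With Ctse, Ren1, Ren2 and Etnk2 (-0.89) left out, 11 of 110 genes in that window (10%) had an unadjusted p under 0.05. The share was 4.61% of 14202 genes elsewhere (Fisher's exact p = 0.0185), 3 of the 11 were higher, and 2.19% of 13193 such windows held as high a share. The window was chosen after Ctse and Ren1 were seen. The exact test treats neighbouring genes as independent, and the windows overlap, those around genes near Ptprc included, so neither share settles it. The Ren1 and Ren2 probes correlated at 0.904 over the 8 arrays of both groups together, where the rise of both in miR-223KO raises the correlation by itself. It thus does not decide whether sequence shared by the renin genes lies behind both. A Ren2 copy carried by some mouse strains could give the same, and the 2 were not separated. That segment cannot carry Nnt, which lies on chromosome 13 and did not pass in limma (adjusted p = 0.981), with groups that overlapped. Were donor DNA to account for Nnt, another remnant of a strain with an intact Nnt would be needed, which was not tested. A response to the loss of miR-223 stays open and untested.

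Male-biased genes lay lower and female-biased genes higher in miR-223KO, a contrast of 0.734 between the list shifts (0.956 on slide 1, 0.421 on slide 2). A lower share of hepatocytes would lower the hepatocyte genes of both lists. The female-biased score instead stood 0.287 (SE 0.14) higher in miR-223KO, beside a male-biased score of -0.442 (SE 0.155). That rise is part of the pattern itself, with an exact permutation p of 0.143 and a shift of only 0.07 on slide 2. It thus does not decide on the share of hepatocytes. With outlier-flagged spots kept, 18 hepatocyte genes shifted by -0.07 against -0.43 for the male-biased genes. A single array is argued against, since the contrast was at least 0.604 without any one array. For a brightness-dependent dye bias, 0 of 100 draws of random lists matched on signal reached the contrast (highest 0.287). The draws used ratios from which loess had already removed a trend with brightness. They could hardly have come out otherwise, so this test does not decide on dye bias. A weaker male pattern of liver transcription in miR-223KO may be the cause, a hypothesis found and tested on the same samples, whose list calls did not hold with an estimated correlation.

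MHC class II, monocyte and macrophage, Kupffer and endothelial genes lay higher in miR-223KO, with a mean shift of 0.222 that was 0.323 on slide 1 and 0.121 on slide 2. A lower share of hepatocytes would raise the markers of every other cell type alike. The rise in score of these 4 lists was 0.254 (SE 0.0746) above that of 5 others, whose mean shift was -0.03. These 5 were the lists of T and NK cells, B cells, neutrophils, stellate cells and cholangiocytes. The 4 and the 5 lists were parted by whether they had shifted, so the gap follows from that choice. It cannot decide on the share of hepatocytes, which stays open for this pattern. A single array is argued against, since the mean shift was at least 0.173 without any one array, although the calls of 3 of these lists ended without WT replicate 1 (adjusted p of 0.112 to 0.141). More of these cells, or a change within them, may account for the pattern, and neither was tested.

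The counts of calls do not exclude chance among the 35 ways to part the 8 arrays into groups of 4. A split and its mirror count once, so a call in another split has no direction of its own and was set against both counts. The 1 gene higher was thus matched in 2 of the 35 splits, the real one included (highest other 1), and so was the 1 gene lower (highest other 1), both times by Nppb in the split that followed the slides. The real split alone gave 2 genes in both directions together. The 13 list shifts were matched in 2 splits (highest other 13, in a split that was uneven over the slides). Of the 18 splits with 2 arrays of each slide in each group, the real one gave 2 genes and 13 lists, and the 17 others gave 0 genes in limma (median 656 at an unadjusted p under 0.05) and at most 9 lists. These 18 are too few for a share under 0.05. The split that followed the slides gave 1 gene and 0 lists by limma and camera, with 1529 genes at an unadjusted p under 0.05, the most of any split, against 772 in the real one. The split of WT replicates 1 and 2 with miR-223KO replicates 3 and 4, even over the slides, gave 1391, so the arrays hold a structure that is not by slide alone. With slide as a block there were 1 gene higher, 1 lower and 12 lists.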

How the results depend on the processing

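Alternatives that kept outlier-flagged spots, kept flagged backgrounds as scanned, allowed 2 unflagged values per group or left Slco1a1 out of its list were chosen after seeing the data, and the others before. Of the list shifts recomputed, 954 kept their direction and side of the threshold, 90 lost the call, 11 gained one and 0 changed sign while called, and of the named genes 2497, 7, 2 and 0 did. A sign that flipped in a value uncalled in both settings was counted as kept. Ctse passed in all 29 alternatives, from 2.27 to 3.13 with adjusted p of 3.32e-05 to 0.0244.

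The count of genes higher was 2 with a normexp offset of 16 and 1 to 2 over the arrays left out (2 without miR-223KO replicate 1). The count of genes lower was 2 with that offset, with Cy5 above background on all 8 arrays, with an adjusted p under 0.10 and with at least 2 unflagged values per group (Slco1a1 and Mup1), and 1 to 2 over the arrays left out (2 without WT replicate 4). It was 0 in limma with the LogRatio (984 at an unadjusted p under 0.05), median centring (541), Cy5 alone (839), the authors' table (1037), the mean of a gene's probes (795) and flagged backgrounds kept as scanned (1024), where Slco1a1 ran from -2.45 to -1.57. With outlier-flagged spots kept, Slco1a1 did not pass (-1.58, adjusted p = 0.222, in a range of 0.000739 to 0.716) and the 1 lower call was an unnamed probe. The count of lists, 13, was 8 with Cy5 alone, 6 with Cy5 above background on all 8 arrays, 0 with an estimated correlation or fry (5 unadjusted in each), and 8 to 13 over the arrays left out (8 without WT replicate 1, WT replicate 4 or miR-223KO replicate 1). Beyond these, the authors' table ended the xenobiotic call (adjusted p = 0.0608), and Cy5 above background on all 8 arrays those of lipid droplet (0.0927), Kupffer (0.0576), macrophage and endothelial genes. Cy5 alone ended those of endothelial (up to 0.094) and oncofetal genes (up to 0.0658, also with no filter), and backgrounds as scanned that of macrophage genes (up to 0.0827). The cause was not tested, except that fewer genes were tested at 11762 with all 8 arrays. Median centring moved the median fold change of all genes from -0.01 to 0.07.

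The replicate numbers did not show a pairing of samples, with correlations of -0.00375, 0.0611, 0.0107 and -0.0217 between samples of one number, and with the number as a block there were 1 gene higher, 1 lower and 12 lists. The test of miR-223 seed sites and its alternatives (8mer sites, matched length) were not run, for lack of sequences. Signal over background limits what can be seen, as Cy5 was well above background on 49.5% to 69.8% of spots, and outlier flags removed 442 of 828 bright genes.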

Other observations

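The test of the reference RNA and the choice of the bright genes below followed sight of the results. With outlier-flagged spots kept, bright liver genes could be read that the comparison had left out, though none of those named here passed. The major urinary protein genes Mup1, Mup2 and Mup3, male-biased and secreted by hepatocytes, stood at -1.20, -1.22 and -1.28 in miR-223KO. Of the other male-biased genes so read, C8a stood at -0.63, while Gstp1 (0.41), Ugt2b38 (0.27) and Selenbp2 (0.17) went the other way. Mup1 passed under another setting chosen after seeing the data, with at least 2 unflagged values per group, where it was the second gene lower. Cyp3a11 and Cyp3a16, cytochromes P450, both stood at 0.95. The male-biased shift was then -0.43 over 21 genes and the female-biased shift 0.34 over 20.

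Signals of liver and reference resembled each other on each array, with a Spearman correlation across genes of 0.931 to 0.962 between Cy5 and Cy3 of one array, against 0.859 to 0.89 on average between the Cy5 of different arrays. The Cy3 of different arrays, from the same reference RNA, correlated at only 0.899 to 0.922 on average. The value within an array thus does not measure the likeness of the RNA alone. Genes are not independent replicates. The mean log2 ratio had an SD of 0.41 over genes, and 8 of 16755 genes lay at least 4-fold from the median. A reference close to liver RNA may account for this small spread of ratios. The median of 6 hepatocyte genes lay only 0.244 above that of 8 other cell types and tissues on the log2 scale, and that of 18 lay 0.234 above it with outlier-flagged spots kept. Single hepatocyte genes lay farther above the reference on that scale, Alb by 1.69 and Apoa1 by 0.64, so the likeness is not complete.

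Y-linked genes were well above background in Cy5 on 8 arrays for Ddx3y and Eif2s3y and on 7 for Uty and Kdm5d, and Xist on 1 WT and 1 miR-223KO array. The first principal components held 20.2%, 19.5% and 14.8% of the variance, and the first had WT replicate 1 at 27.9 and WT replicate 4 at -25.9. On it the WT samples of slide 1 lay at 11.3 and above and those of slide 2 at -19.7 and below. The miR-223KO samples went the other way, at -0.137 and -6.57 on slide 1 and 10.7 and 2.4 on slide 2. WT replicates 1 and 2 and miR-223KO replicates 3 and 4 thus lay above 0, as parted in the split that gave 1391 genes. The other arrays far out were miR-223KO replicate 3 on the second at -36.9 and miR-223KO replicate 4 on the third at 32.5. Across genes, the authors' log2 fold change correlated with that computed here at 0.826 (Spearman 0.853).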
